A study of Homo sapiens with 5 samples.

How the data were processed

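Expression was measured on 5 single-colour Illumina HT-12 bead arrays, 1 for each of weeks 0, 2, 4, 6 and 8 of differentiation of the human embryonic stem cell line H9. Per the labels, total RNA was extracted with Trizol, cleaned on columns with a DNase step, turned into biotin-labelled cRNA and hybridised, and all 5 arrays lay on 1 chip. The labels describe every sample as a non-replicate. The software that read the arrays is not given in the sources used here.

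The main input was the table of signals before normalization, in which the deposited values are each probe's mean bead intensity on a linear scale, per the file headers and the values. The lowest deposited signal on an array was between 90.0 and 98.7, so no background had been subtracted. Beside each signal the deposited table holds a detection score, a fraction from 0 to 1 per the file headers, which was read as 1 minus the detection p-value because it rises with the signal to 1. A second deposited table holds the authors' processed intensity of the same arrays, also on a linear scale. Its columns had medians of 133.1 at week 0 and 133.2 at the other weeks and shared their lowest and highest values, as quantile normalization would give. Its values followed the unnormalized signals of the same array with a Spearman correlation across probes of 0.999, so scale and direction were settled and no centring was seen. The method behind that table is not given in the sources used here.

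Signals were background corrected and normalized with the neqc function of limma 3.58.1 in R 4.3.3. This function fits a normal-exponential model whose background is inferred from the detection p-values, adds an offset of 16, quantile normalizes the 5 arrays and takes log2. A probe counted as above background where its detection p-value was under 0.01. A value below background was set at the higher of its own value and the lowest value above background on that array, so a fold against it is a lower bound and is written as "at least". Later steps used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

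Of the 47317 probes in the files, 30110 had 1 gene symbol in the platform annotation, 8 had several and 17199 were not listed and are unnamed here. Symbols were updated through Entrez identifiers for 30071 probes, and the other 39 kept the annotation's name. The named probes cover 20045 genes. XIST and Y-linked probes, 143 in all, were left out. Of the genes that remained, 12999 were above background on at least 1 array and entered the comparisons, each with the probe of highest mean. Unnamed probes above background on an array numbered 4934 and were not analysed here.

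With 1 array per week there is no spread between replicates, so no test was run and no p-value or error is given for a gene. A gene was called higher or lower where 2 arrays differed by at least 2-fold (1 on the log2 scale) and the brighter array was above background. A transient gene was at least 2-fold above, or below, both week 0 and week 8 on an array between them. These calls compare single arrays, and the spread between cultures is unknown. Each of 31 gene lists was summarised by the median log2 difference of its members and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. The steps were tested on simulated arrays for week 8 against week 0, with noise of SD 0.1 on the log2 scale. All 50 probes lowered 4-fold were called, as were 48 of 50 raised 4-fold, 49 of 50 raised 2.5-fold and 43 of 50 lowered 2.5-fold, and 4 of 30981 unchanged probes were called. The noise was set and not estimated, and the changed probes were drawn from those with the lowest detection p-value on the week 0 array. These shares therefore check the steps on clearly detected probes and give no rate of false or missed calls for the real arrays.

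The lists, the size of a call, the alternatives and the rule for named genes were fixed before the data were examined. The rule names a set of 13 genes in any case, the 10 largest increases and decreases from week 0 to week 8 and the 5 largest bounds each way, up to 4 members of each list, the 3 largest changes each way in each step between neighbouring weeks and the 5 largest transient increases. Other members named here to complete a count of 5 or fewer, or to give the values of single HLA genes, were chosen after their values were seen. The alternatives were no background correction, scaling to a common 75th percentile in place of quantile normalization, an offset of 50, a detection p-value limit of 0.05, only genes above background on all 5 arrays, the mean of a gene's probes, and the authors' processed values. Where a gene had several probes, they often differed: of 616 genes called at week 8 on the main probe and having another probe above background at weeks 0 and 8, 528 (85.7%) changed in the same direction on the other probe and 351 also by 2-fold.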

Results

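H9, an established human embryonic stem cell line, was grown in E6, a defined medium, and total RNA was sampled at week 0, before differentiation, and at weeks 2, 4, 6 and 8 of differentiation toward cells resembling the epithelium of the cornea. There was 1 array per week and no replicate, so each difference is one between 2 arrays. Between 16993 probes (week 0) and 18358 probes (week 8) were above background. The median signal of those probes was 2.90 times that of the probes below background at week 0, and 2.67, 2.67, 2.62 and 2.72 times at weeks 2, 4, 6 and 8. The arrays moved steadily away from week 0, with a Pearson correlation across 21928 probes of 0.90 at week 2, 0.87 at week 4, 0.84 at week 6 and 0.82 at week 8. Weeks 6 and 8 were the closest pair of arrays, at 0.98. Probes are not independent replicates, and these correlations describe the arrays alone.

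The first comparison sets each week against the undifferentiated cells and asks which programmes the cells left and entered over the 8 weeks. By week 8 most measured genes of the pluripotent state and of cell division were lower, and several keratins (KRT1, KRT5, KRT13, KRT14, KRT15 and KRT16), desmosome genes, eye-field and lens genes, pigment genes and genes of stromal matrix were higher. Of 12337 genes above background at week 0 or week 8, 2067 were at least 2-fold higher and 1898 at least 2-fold lower at week 8, and 765 and 404 passed 4-fold. At week 2 the counts were 1244 higher and 1085 lower, at week 4 they were 1657 and 1359, and at week 6 they were 1902 and 1691. Of the genes higher at week 8, 40.4% were already called higher at week 2, 54.8% at week 4 and 78.6% at week 6, and for the lower genes the shares were 38.4%, 50.6% and 75.7%. The split between directions depended on scaling and on the filter. Higher genes made up 53.4%, 54.9%, 52.9% and 52.1% of the calls at weeks 2, 4, 6 and 8, but 46.3%, 41.5%, 39.5% and 41.9% when arrays were scaled to a common 75th percentile. With only genes above background on all 5 arrays, 1282 genes were higher and 1306 lower at week 6, and 1324 and 1502 at week 8. Without background correction the week 8 counts were 1251 higher and 992 lower.

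**Figure D1:**
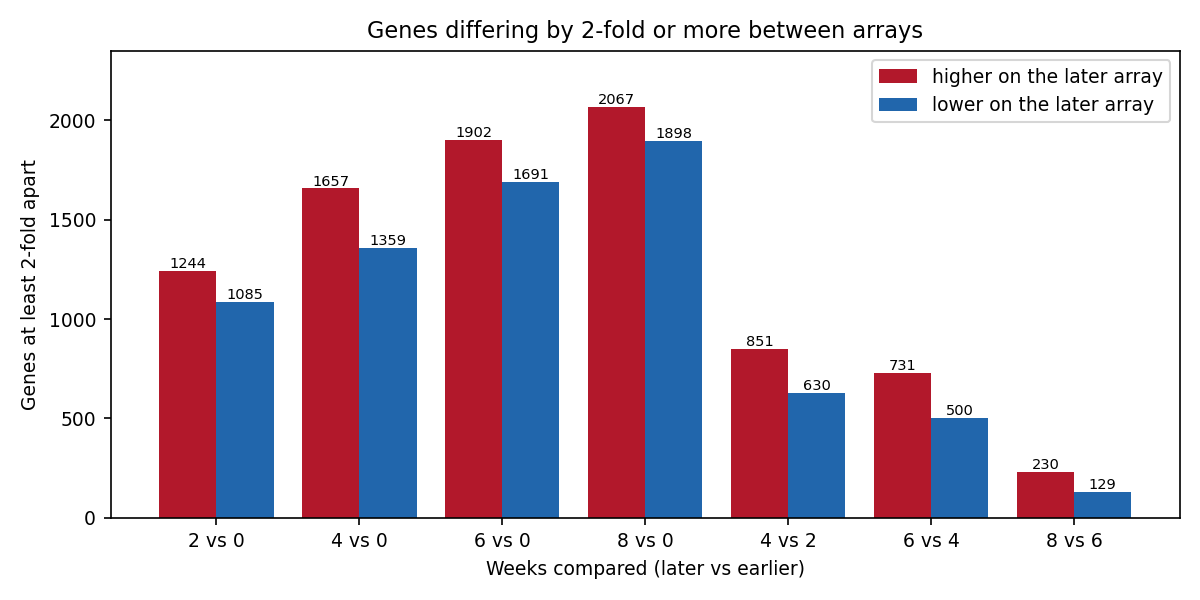
Number of genes (vertical axis) at least 2-fold higher or lower on the later of 2 arrays, for each pair of weeks compared (horizontal axis), with 1 array per week. Against week 0 the counts grow from 1244 higher and 1085 lower at week 2 to 2067 and 1898 at week 8, and the step from week 6 to week 8 has the fewest, 230 and 129.

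Genes of the pluripotent state fell early and far. POU5F1, a core transcription factor of pluripotency, fell 15.2-fold by week 2 and at least 62.4-fold by week 8, when it was below background. NANOG, another core factor, fell 22.4-fold by week 2 and at least 29.7-fold by week 8. The RNA-binding protein gene LIN28A fell more slowly, 2.13-fold at week 2 and at least 202-fold at week 8, and the DNA methyltransferase gene DNMT3B fell 73.0-fold by week 8. Among the largest decreases measured on both arrays were also DPPA3 (110.0-fold), POLR3G (72.6-fold), L1CAM (60.6-fold), SALL4 (45.2-fold), SPRY4 (22.6-fold), ALPL (22.2-fold), HELLS (20.3-fold), ZFP42 (18.3-fold) and SLC7A3 (17.9-fold). ZSCAN10, TRIM71 and USP44 fell by at least 55.9-fold, 39.0-fold and 37.9-fold. Of 19 measured members of the pluripotency list, 14 fell and none rose by week 8, and the list median of -3.17 lay below all 10000 random lists. DPPA4, UTF1, GDF3 and TERT of that list were below background on all 5 arrays and were not measured. SOX2, which also serves neural and eye progenitors, differed by -0.87 at week 8 and was not called, although its difference was -1.34 with scaling to the 75th percentile.

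Cell division genes fell as well, and later. The proliferation list had a median of -0.46 at week 2 and -2.41 at week 8, when 22 of its 26 measured members had fallen and none had risen. The replication helicase genes MCM4 and MCM5 fell 11.9-fold and 11.1-fold by week 8, the mitotic checkpoint kinase gene BUB1 fell 8.85-fold and the nucleotide synthesis gene RRM2 fell 7.87-fold. CDKN1A, which encodes the cell cycle inhibitor p21, rose 11.6-fold by week 2 and 47.0-fold by week 8. CDKN2B, another inhibitor gene, rose at least 9.70-fold and TP53INP1 rose 3.50-fold. In the list of cell cycle arrest and senescence 6 of 14 measured members rose, 2 fell and 6 were not called at week 8. The falling members were GADD45G and CDKN2D, and for CDKN2D the difference of -2.03 shrank to -0.16 on the mean of its probes.

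Of the keratins of basal epithelium, KRT5 rose from week 4 onward, and KRT14 and KRT15 were called higher than at week 0 at weeks 6 and 8. KRT5 and KRT14, the keratin pair of basal epithelial cells, were below background at weeks 0 and 2. KRT5 was at least 5.50-fold above week 0 at week 4, at least 34.2-fold at week 6 and at least 6.64 on the log2 scale at week 8. KRT14 was at least 18.0-fold higher at week 6 and at least 17.3-fold higher at week 8, and KRT15 at least 2.60-fold and at least 10.3-fold. Of 13 measured members of the basal and limbal list, 7 rose by week 8, among them TNFRSF19 (28.9-fold), and FZD7 fell. The list median was 1.23, at percentile 99.955 of the random lists. In the corneal epithelium list 26 members had a named probe and 15 were measured. Of these 15, 11 rose, TKT fell, and the median of 2.399 lay above all random lists. KRT16 rose 302-fold, the largest increase among genes above background at both weeks, the retinaldehyde dehydrogenase gene ALDH1A1 rose 69.1-fold, and the transcription factor genes PAX6 and KLF4 rose at least 46.4-fold and at least 14.5-fold. KRT3 and KRT12, the keratins of differentiated corneal epithelium, and the limbal transporter gene ABCG2 were below background on all 5 arrays, and TP63 had no named probe. ALDH3A1, KRT24, KRT78, AQP5, GJA1, GJB2, SLURP1, CRTAC1 and ADH7 of the corneal list were also below background on all 5 arrays. The corneal count and median therefore describe the detected members alone. A reading below background does not show that a gene was not expressed. DPPA4, UTF1, GDF3 and TERT of the pluripotency list also read below background on all 5 arrays, that of the undifferentiated cells included. A further probe of PAX6 that was above background on all 5 arrays differed by 0.06 on the log2 scale between weeks 0 and 8.

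Genes of other surface epithelia rose too. In the conjunctival and epidermal list 8 of 14 measured members rose by week 8 and none fell, with a median of 1.31 at percentile 99.98. SPRR3 rose at least 30.05-fold, KRT13 at least 12.6-fold, KRT1 9.22-fold and the protease gene KLK5 7.06-fold. In the list of desmosomes and hemidesmosomes 9 of 16 rose and none fell, with a median of 1.48 above all random lists, and PKP1 rose at least 12.1-fold, DSC2 9.64-fold, PERP 8.30-fold and COL7A1 at least 7.81-fold. Early surface ectoderm genes had 8 of 14 measured members higher and EPCAM lower, with a median of 1.44 above all random lists. TFAP2A and MSX1, transcription factor genes of early ectoderm, rose at least 65.1-fold and at least 42.7-fold, and GRHL2 at least 7.17-fold. CDH1, the gene of E-cadherin, read at least 8.49-fold higher, but its probe was below background at week 0, at 4.42 on the log2 scale, although human embryonic stem cells are known to express this gene. With only genes above background on all 5 arrays the early surface ectoderm median turned to -0.28. Part of the tight junction and polarity genes fell at first. None rose at weeks 2, 4 and 6, while 7 of 18 measured members fell at week 2 (median -0.72), 10 of 16 at week 4 (-1.27) and 6 of 18 at week 6 (-0.38), and the medians at weeks 2 and 4 lay below all random lists. At week 8 CLDN4 (at least 11.4-fold) and RAB25 (2.20-fold) rose, the splicing regulator genes ESRP1 and ESRP2 fell 3.62-fold and 2.04-fold, and 14 of the 18 measured members were not called. RAB25 was not called with scaling to the 75th percentile (0.83).

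Genes of the eye field, lens, stroma and fibroblast, and neural crest and pigment lists rose beside the epithelial genes. Not all of these genes are particular to the eye, and TTR is also in the endoderm list. In the eye field and retina list 13 of 18 measured members rose by week 8, SIX6 fell, and the median of 1.64 lay above all random lists. LHX2 and MEIS2, transcription factor genes of the early eye, rose at least 65.9-fold and at least 38.2-fold. TTR, which encodes a carrier of thyroid hormone and retinol-binding protein, rose by at least 9.33 on the log2 scale. In the lens list 7 of 10 rose and none fell, with a median of 1.85 above all random lists. The crystallin genes CRYAA, CRYAB, CRYGS and CRYBA4 rose at least 125-fold, 15.7-fold, 10.3-fold and 5.31-fold. In the stroma and fibroblast list 18 of 22 rose, THY1 fell, and the median of 3.54 was the highest of the 31 lists. The matrix proteoglycan genes DCN and LUM rose at least 181-fold and at least 131-fold, PDGFRA at least 34.4-fold and VIM 29.3-fold. A second probe of DCN that was above background on all 5 arrays differed by 0.37 on the log2 scale. In the neural crest and pigment list 9 of 12 rose and none fell, with a median of 2.85 above all random lists. The melanin synthesis genes TYRP1 and TYR rose at least 208-fold and at least 21.9-fold, and MLANA and PMEL at least 20.2-fold and 13.6-fold.

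Genes of neurons and mesenchyme were also higher at week 8 than at week 0. In the neural list 10 of 19 measured members rose and NES fell, with a median of 1.01 at percentile 99.92, and NEUROG2, STMN2, SNAP25 and MAPT rose 21.3-fold, 20.3-fold, at least 9.78-fold and at least 5.86-fold. In the EMT and mesenchymal list 10 of 12 rose and none fell, with a median of 2.18 above all random lists. This list is not independent of those above, since TWIST1, VIM, FN1 and SPARC are also in the stroma list and SNAI2 in the neural crest list. The matrix genes TGFBI and SPARC rose 20.7-fold and 7.87-fold, and the transcription factor gene SNAI2 at least 7.79-fold. The other genes among the 10 largest increases above background at both weeks were IGFBP5 (110.1-fold), KRTCAP3 (105-fold), WLS (75.6-fold), HES3 (67.9-fold), TXNIP (67.3-fold), TMEFF2 (64.5-fold) and COL16A1 (59.0-fold). The largest bounds beside TTR and TYRP1 were those of ANXA1 (at least 264-fold), COL2A1 (at least 244-fold) and CRY2 (at least 195-fold).

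Among antigen presentation genes B2M rose and 3 class II genes fell. B2M, the light chain of HLA class I, differed by -0.03 at week 2 and 0.06 at week 4 on the log2 scale, and rose 3.07-fold by week 6 and 4.73-fold by week 8. It was the single called gene among 15 measured members of the class I list at week 8, where the other 14 included HLA-C (-0.42), HLA-E (-0.61), HLA-F (0.70), HLA-G (-0.08) and TAP1 (0.95). The class I median was -0.08, and 0.70 with only genes above background on all 5 arrays. At week 2 the class I list held 1 higher and 4 lower members, HLA-C (1.29) against TAP1 (-2.95), TAP2 (-1.28), PSMB8 (-2.03) and PSMB10 (-1.82). Another probe of HLA-C at week 2 differed by -0.28 from the higher of weeks 0 and 8. In the class II list 3 of 10 measured members fell by week 8 and none rose: HLA-DMB fell 6.57-fold, HLA-DPB1 at least 3.58-fold and CD74 2.04-fold. The class II median was -0.68, at percentile 0.67 of the random lists. In the interferon list 5 of 21 rose and 2 fell. IFI6 rose 10.2-fold, IFI44 at least 3.24-fold, IFI44L 2.87-fold, IFI27 2.84-fold and IFIH1 also rose, while ISG20 fell by 1.41 and MX2 fell by 1.06 on the log2 scale. On the mean of its probes IFI44L differed by 0.24.

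Genes of several signalling pathways were higher. In the retinoic acid list 7 of 10 measured members rose by week 8, with a median of 1.66 at percentile 99.97. The retinoic acid synthesis genes ALDH1A3 and RDH10 rose 16.9-fold and 15.8-fold, whereas CYP26A1, which degrades retinoic acid, fell 5.23-fold, a difference of -0.43 on the mean of its probes. In the WNT list 12 of 23 rose and SFRP1, SFRP2, FZD7 and TCF7L1 fell, with a median of 1.55 above all random lists that turned to -0.38 with only genes above background on all 5 arrays. RSPO3 rose at least 19.2-fold, LEF1 16.5-fold, DKK1 at least 16.2-fold and WNT5A at least 11.2-fold. In the BMP and TGF-beta list 10 of 17 rose and ID4 and SKIL fell, with a median of 1.31 at percentile 99.99, and SMAD6 rose by 2.81 on the log2 scale, GREM1 at least 4.82-fold and BMP7 4.77-fold. In the Notch list HEY1 rose 14.3-fold, JAG1 at least 7.48-fold, NOTCH3 2.30-fold, NOTCH2 2.20-fold and HES5 by 1.01 on the log2 scale, and the other 9 of 14 measured members were not called. NOTCH3 was not called with scaling to the 75th percentile (0.89).

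**Figure D2:**
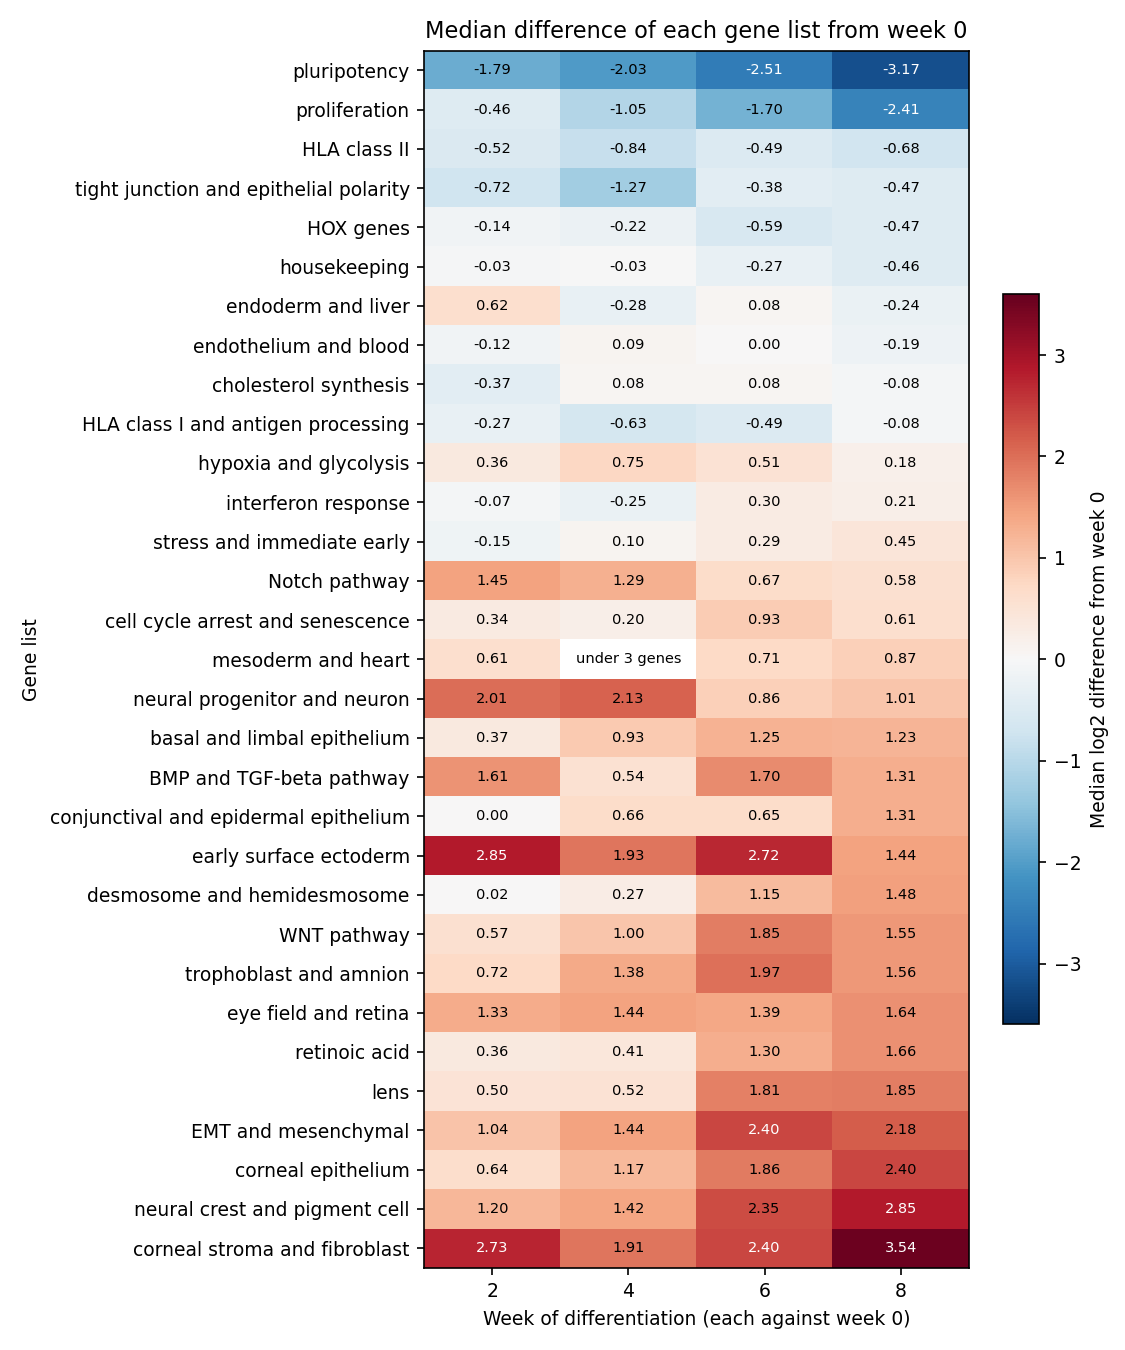
Median log2 difference from week 0 of each of 31 gene lists at weeks 2, 4, 6 and 8, with 1 array per week. At week 8 the stroma and fibroblast list lies highest at 3.54 and the pluripotency list lowest at -3.17.

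The comparison of week 2 with week 0 shows what changed first. Pluripotency genes had fallen, and many genes of early ectoderm, stroma and neurons had risen, while KRT5, KRT14 and KRT15 were still below background. In the pluripotency list 13 of 19 measured members fell, with a median of -1.79 below all random lists. The 3 largest decreases above background at both weeks were NANOG (22.4-fold), CYP2S1 (22.0-fold) and USP44 (21.1-fold), and SOX2 fell 2.44-fold. The largest increases above background at both weeks were IGFBP5 (74.9-fold), WLS (65.8-fold) and STMN2 (63.4-fold). TFAP2A rose at least 104-fold and MSX1 at least 43.2-fold, and the early surface ectoderm median was 2.85, with 6 of 11 members higher and 2, KRT18 and EPCAM, lower. With only genes above background on all 5 arrays that median turned to -0.52. In the eye field and retina list 6 of 11 rose and SIX6 fell, with a median of 1.33 at percentile 99.98, and MEIS2 rose at least 29.5-fold. In the stroma list 17 of 20 rose and THY1 fell, with a median of 2.73, and in the neural list 14 of 20 rose and SOX3 fell, with a median of 2.01, both above all random lists. In the desmosome list none of 13 rose at week 2.

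The step from week 2 to week 4 follows the cells after the first changes. Part of the corneal epithelium list and part of the eye-field genes rose, with PAX6 up 23.7-fold and LHX2 at least 147-fold. In the corneal epithelium list 7 of 13 measured members rose and none fell, with a median of 1.15 above all random lists, and in the eye field list 7 of 13 rose and TTR, POU4F2, EYA1 and EYA2 fell. KRT16 rose 26.1-fold, and the 3 largest increases above background at both weeks were GNPTG (70.3-fold), HES4 (61.1-fold) and TMEFF2 (27.1-fold). The 3 largest decreases above background at both weeks were APOA1 (26.1-fold), POU4F1 (21.2-fold) and ACTN3 (12.5-fold), while NNAT and CSRP3 dropped below background, by at least 302-fold and at least 62.3-fold. In the endoderm list 7 of 13 fell and none rose, with a median of -1.12 below all random lists. In all, 851 genes rose and 630 fell, and with only genes above background on all 5 arrays the counts were 512 and 369.

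The step from week 4 to week 6 asks how epithelial and neural genes moved in the middle of the course. Neural genes fell while lens, desmosome and pigment genes rose. In the neural list 15 of 20 measured members fell and ELAVL4 rose, with a median of -1.499 below all random lists, and STMN2 fell 5.50-fold. Lens genes had 8 of 11 members higher and none lower (median 1.43), desmosome genes 8 of 17 higher and none lower (0.76), and neural crest and pigment genes 8 of 14 higher and SOX9 lower (1.08), each above all random lists. KRT14 rose 9.45-fold, KRT5 6.21-fold and DCN 9.46-fold, and MLANA at least 21.3-fold. The 3 largest increases above background at both weeks were TTR (88.5-fold), CRY2 (51.4-fold) and LGALS7 (29.9-fold), and the 3 largest decreases of that kind were GNPTG (51.1-fold), DLX1 (37.3-fold) and INSM1 (22.6-fold). In all, 731 genes rose and 500 fell, and 387 and 328 with only genes above background on all 5 arrays.

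The step from week 6 to week 8 was the smallest, with 230 genes higher and 129 lower. The 3 largest increases above background at both weeks were S100A9 (8.87-fold), S100A8 (8.75-fold) and the protease gene KLK11 (8.54-fold). In the conjunctival and epidermal list 7 of 14 measured members rose and none fell, with a median of 0.91 above all random lists, and KRT13 rose 4.47-fold. KRT15 rose 3.95-fold and KRT5 2.93-fold, while KRT14 differed by -0.06 on the log2 scale. The 3 largest decreases of that kind were EGR1 (6.47-fold), CYP26A1 (5.75-fold) and RNA28SN5 (5.62-fold), a ribosomal RNA gene. In the proliferation list 6 of 25 fell and none rose. With only genes above background on all 5 arrays, which leaves out genes first seen late, 55 genes rose and 98 fell.

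Some genes were brighter on a middle array than at both ends of the course. Of the genes measured, 570 were at least 2-fold higher than at both ends of the course on an array between them, 267 of them with their peak at week 2, 277 at week 4 and 26 at week 6. Genes at least 2-fold lower than at both ends on such an array numbered 327, and a few, such as SOX3 and ERBB3, were in both sets. By value or lower bound, the largest rises above both ends were those of NNAT (at least 8.17 on the log2 scale), POU4F1 (at least 6.24), SST (at least 6.17) and CSRP3 (at least 5.89), all at week 2, and GNPTG (5.75) at week 4. The first 4 were below background at week 0, so their order is that of bounds. A second probe of NNAT rose by at least 3.05 on the log2 scale. POU4F1, a transcription factor gene of sensory neurons, and the peptide hormone gene SST were at least 75.5-fold and at least 71.9-fold above week 0 at week 2. POU4F1 was below background at weeks 0, 6 and 8. NNAT and CSRP3 were above background at week 2 alone.

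**Figure D3:**
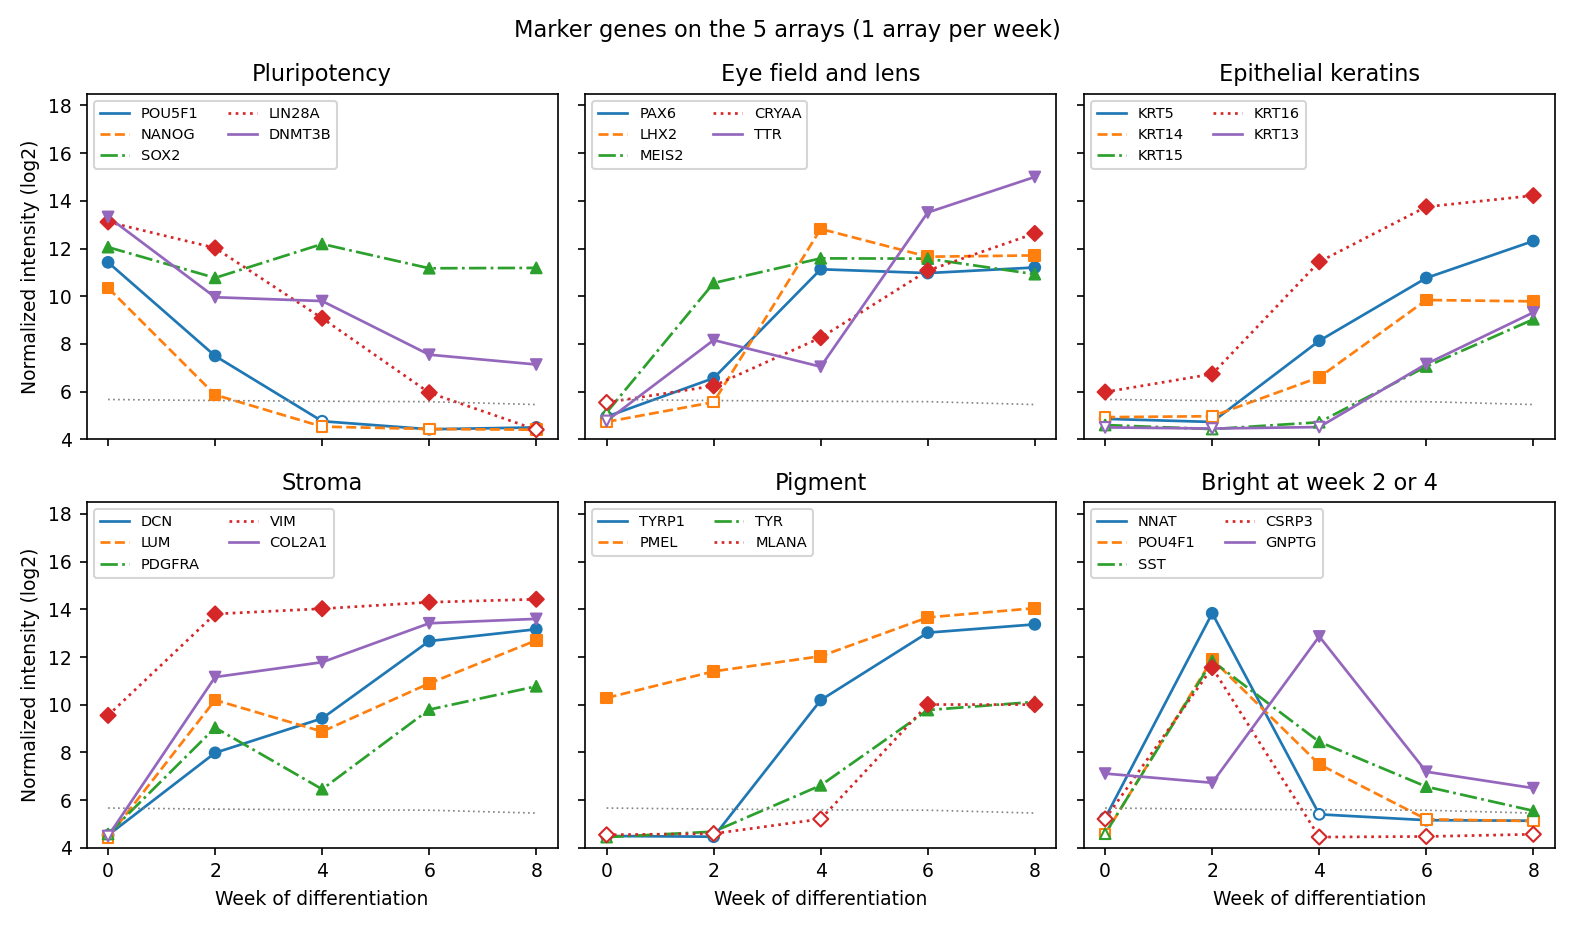
Normalized log2 intensity of selected genes by week, in 6 panels by group, with filled points above background, open points below it and a grey dotted line at the lowest value above background on each array. POU5F1 falls from 11.42 at week 0 to below background, and KRT16 climbs to 14.22 at week 8.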

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

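All alternatives reported here were chosen before the data were examined. Scaling to the 75th percentile, a detection limit of 0.05 and the mean of probes left all 16 counts of genes within 1.5 times. Leaving the background in pulls ratios toward 1 by construction, and each count was lower without background correction. Each was also lower with the authors' values, whose normalization is not given in the sources used here, and the cause was not tested. Without background correction and with the authors' values in turn, genes higher and lower against week 0 numbered 642 and 479, and 645 and 455, at week 2. At week 4 they were 983 and 601, and 983 and 589. At week 6 they were 1147 and 830, and 1145 and 805, and at week 8 they were 1251 and 992, and 1242 and 944. From week 2 to 4 they were 425 and 236, and 422 and 240. From week 4 to 6 they were 325 and 220, and 306 and 213, and from week 6 to 8 they were 82 and 30, and 79 and 33. Transiently higher genes numbered 283 and 275, and transiently lower genes 100 and 88. Lists with a week 8 median of at least 1 either way were 9 and 9, against 17 of 31 with the main settings.

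An offset of 50 gave 416 genes lower from week 2 to 4, 146 higher and 76 lower from week 6 to 8 and 200 transiently lower. Keeping only genes above background on all 5 arrays drops, by construction, genes that start below background. It gave 819 genes higher at week 2 against week 0, and at week 8 it turned the majority, with 1324 higher and 1502 lower (1282 and 1306 at week 6). It also gave 512 higher and 369 lower from week 2 to 4, 387 higher and 328 lower from week 4 to 6, 55 higher from week 6 to 8 and 278 transiently higher. With that filter the early surface ectoderm median turned from 2.85, 1.93, 2.72 and 1.44 at weeks 2, 4, 6 and 8 to -0.52, -0.58, -0.54 and -0.28, and the WNT median from 1.85 and 1.55 at weeks 6 and 8 to -0.23 and -0.38, and the mesoderm, lens and HOX lists had too few members for a median. Under 75th percentile scaling the median of all genes moved to -0.11, -0.19, -0.19 and -0.21 at weeks 2, 4, 6 and 8, against -0.03, -0.05, -0.04 and -0.05, and changes there are relative to that shift. Of the named genes' results, 140 kept their call with that scaling, 2 lost it and 1 gained it, and 15 lost it without background correction. Signal over background limits what small differences can show, since the median signal above background was 2.62 to 2.90 times that below it.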

Other observations

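The sibling-probe test, the sensory neuron test and the test of other probes seen on any array were chosen after the result was seen, and the other tests were written down before.

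Markers of further lineages were mixed at week 8. In the trophoblast and amnion list 27 members had a named probe and 12 were measured. Of these 12, 7 rose and none fell, with a median of 1.56 at percentile 99.99. VTCN1 rose at least 27.2-fold, the iron exporter gene SLC40A1 at least 18.3-fold, XAGE2 at least 11.7-fold and the aromatase gene CYP19A1 at least 5.54-fold. Other members, among them CGA, CGB5, GCM1, ERVW-1, HSD3B1, INSL4, PSG3 and ELF5, were below background on all 5 arrays. TFAP2C and GATA2 are also in the early surface ectoderm list. In the endothelium and blood list TEK fell 10.1-fold, CLDN5 7.69-fold, ESAM 2.72-fold and ENG at least 2.47-fold, none of 13 rose, and 9 were not called. In the endoderm list TTR, CER1 and CXCR4 rose and FOXA2 (9.19-fold) and AFP fell, with 10 members measured. On the mean of their probes CER1 differed by 0.85 and CXCR4 by 0.64. In the mesoderm and heart list MESP1 and MEOX1 rose by at least 1.97 and 1.85 on the log2 scale, and 3 of 5 were not called. None of the 3 measured HOX genes was called.

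Stress and metabolic genes moved in both directions. In the stress and immediate early list 5 of 22 measured members rose and 3 fell by week 8. FOS rose 10.9-fold, DDIT3 4.67-fold and HSPA1A, JUNB and IER2 by 1.67, 1.55 and 1.24 on the log2 scale, while CHAC1 fell at least 5.85-fold, the asparagine synthetase gene ASNS 3.50-fold and MT1X fell by 1.41. In the hypoxia and glycolysis list 7 of 19 rose and ADM, HK2 and PGAM1 fell, and NDRG1 rose at least 31.6-fold, VEGFA 5.14-fold, ANKRD37 4.91-fold and P4HA1 3.86-fold. In the cholesterol list INSIG1 (3.98-fold) and HMGCS1 (at least 2.14-fold) rose, and 12 of 14 were not called. On the mean of its probes INSIG1 differed by 0.87. In the housekeeping list 11 of 15 were not called, and HPRT1, IPO8, TFRC and TUBB fell 2.66-fold, 2.61-fold, 2.42-fold and 2.18-fold.

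Probes of gene families picked by name as broadly used, such as ribosomal and proteasome genes, often read near background: 91 of 403 (22.6%) had a mean under 6.5 on the log2 scale, as did every probe of 33 of 258 genes. These counts include genes of restricted or induced use, such as COX6B2, PSMB11, PSMB8 and PSMB9, so they overstate the share. Exchange of probes between genes is argued against, because 0.169% of the 591 probes of gene families silent outside their own organ (95% exact interval 0.00 to 0.939) reached 8 on an array, where exchange would give 10.7%, or 4.81% if only dim probes with a bright sibling were exchanged. Genes not expressed in these cells could also give dim probes. Of the 70 dim probes with a sibling, 41 (58.6%) had one that reached 8, which argues against a lack of expression for the genes of those 41. The 95% exact interval of 46.2 to 70.2 includes 50%, the limit set for this test. Lack of expression therefore stays open for the other dim probes. The interval treats probes as independent, although several dim probes share a gene and a sibling, such as those of EIF4E and PSMD12, so it may be too narrow. Probes that hybridise weakly, among them perhaps that of CDH1, stay open too and were not tested.

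TTR and pigment genes were both higher at week 8 than in the undifferentiated cells, TTR at 15.001 on the log2 scale. They did not move together throughout. From week 2 to week 4 TTR fell 2.17-fold while the pigment gene TYRP1 rose at least 23.7-fold. Both rose from week 4 to week 6, TTR 88.5-fold and TYRP1 7.11-fold. Cells resembling retinal pigment epithelium may contribute: the list of their markers had a median difference of 1.052, just over the limit of 1 set for this test, 7 of 13 measured members rose and LRAT fell, and 5 of the members are also in the lists above. Cells resembling choroid plexus, which is rich in TTR, are another possibility. Their list had a median of 1.699 with 6 of 10 higher, and HTR2C was at least 29.9-fold higher. None of the 10 is in the other lists. The neural crest melanocyte list had a median of 1.19 with 3 of 6 higher (SOX10, MC1R and TFAP2B), too few to decide, and 4 are in the lists above. These are hypotheses from bulk RNA, which cannot separate a mixture from cells that express both sets.

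Genes brighter on a middle array than at both ends could reflect cells present for a short time or faults of single probes. The set of 570 is not limited to genes bright on 1 array. LHX2, for example, peaked at week 4 at least 7.15 above week 0 on the log2 scale, but only 1.11 above week 8. A short presence does not describe such genes. A fault of single probes is argued against as the cause of the whole set. Of the 570 genes, 117 had another probe above background on the peak array, a condition that favours a rise. That probe had a median rise of 0.926 on the log2 scale (1.51 on the main probe), and 57 reached 2-fold. A further check dropped that condition and averaged, per gene, all other probes above background on any array. Over 132 genes the median of this mean rise was 0.711, and 51 reached 2-fold. A fault of single probes stays open for genes whose other probe did not rise, such as HDAC9 (-0.10), STIM2 (-1.10) and FIGNL2 (-1.10), singled out after their values were seen, and for GNPTG, CSRP3, POU4F1, SST and APOA1, which have 1 named probe. Sensory neuron-like cells at week 2 stay open as a contributor. Without POU4F1 and SST the list had a median rise of 1.165 over both ends, and 5 of 9 members rose (NEUROG1, EYA1, SNCG, ONECUT2 and TLX3). The test cannot decide, because these 5 are themselves transient genes with their peak at week 2. Of weeks 0, 2 and 8, SNCG and TLX3 were above background at week 2 alone. PRPH rose from 4.90 at week 0 to 8.95 at week 2 but lay lower than at week 8, by -2.37. Genes of other lineages rose at week 2 too: in the endoderm list 6 of 14 measured members rose and 1 fell, with a median of 0.62. As 4 of the 9 sensory neuron members are in the lists above and 1 array was measured, a faulty array or a passing cell type cannot be separated by replicates.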
